A study of Homo sapiens with 4 samples.

How the data were processed

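Total RNA of 4 cultures of T47D-MTVL cells, 2 given 10 nM R5020 and 2 given ethanol vehicle for 6 h, was profiled on Illumina BeadChip arrays. Per the labels, the RNA had integrity numbers from 9.2 to 9.8, and 200 ng per sample was amplified and biotin-labelled. The labels give the group and the replicate number of each array and call the replicates biological.

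The values are the authors' normalized expression values on a log2 scale, as deposited, rounded to 2 decimals, with 1 column per array. Scanner output came from BeadStudio and was processed with the R package lumi, per the submitters' processing notes, and neither version is given. The background correction, the normalization method and whether the scale is a plain log2 or a variance-stabilising transform are not given in the sources used here. Values run from a floor near 7, where the median probe lies at 7.29, and the 4 column medians were 7.29, 7.29, 7.29 and 7.28. A fold change here is the power of 2 of a difference on that scale, and it can understate the change of dim genes. Detection p-values and scanner files were not used here. The number of arrays, 2 per group, limits the precision.

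Of 22185 probes listed, 8 had no value on any array and 22177 were kept. By the platform annotation, 19708 had 1 gene symbol, 0 had several and 2469 had none. Symbols were updated through gene IDs, of which 19688 probes matched a table of human RefSeq genes (assembly GRCh38.p14), used for names only. The 16577 genes were each represented by the probe with the highest mean over all 4 arrays, and 2268 genes had more than 1 probe. Among other probes of called genes that lay above the probe median, 218 of 243 changed in the same direction as the chosen probe, 91 of them past the threshold, and 1 passed it in the opposite direction. That was a probe of N4BP2L2, named after its values were seen, with a log2 change of 0.40 against -0.88 for the chosen probe.

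R5020 was compared with vehicle by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, two-sided), with group as the term, no filter on dim probes and no further normalization. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The moderated test had 4.65 degrees of freedom, of which 2.65 came from the prior. The 27 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it, as was fry, which asks whether a list's genes move on balance one way and compares them with no other genes. With a preset correlation camera takes its degrees of freedom from the number of genes, but with an estimated one from the 4 arrays. Its p-values then rise whatever the correlation. Members of the lists without a probe used here were not analysed here. List medians were also set against 10000 random lists of the same size matched on mean signal.

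The comparison, the lists, the alternatives and the genes to be named were fixed before the data were examined. Named genes are the 12 called genes with the largest increase and the 12 with the largest decrease among those whose groups do not overlap, up to 4 members with the largest absolute change in each list described, any member of the progestin target list, and PGR. A gene named outside this rule is said to have been chosen after its values were seen.

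Alternatives were a filter on dim probes, quantile normalization, median centring, an intensity trend or a robust prior in eBayes, the replicate number as a block, the mean of all probes of a gene, all probes as features, an adjusted p under 0.01, a fold change of at least 1.5, an offset of 50 on the linear scale, camera on ranks, and leaving out each array in turn. After seeing the data, 3 were added: array weights per group, taking off the median log2 change of genes above the probe median, and an intensity trend in the fits without an array or with the block.

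The steps were tested on simulated data drawn for the same 16577 genes and 4 arrays, with 200 genes changed in each of 20 runs. For R5020 against vehicle, 91.8% of changes of 0.5 on the log2 scale were recovered, 99.6% of changes of 1 and 100% of changes of 2, and 3.24% of calls were false. In simulated lists, a list shifted by 0.2 was found in 20 of 20 runs, and 2 of the unshifted lists were called over all runs. Simulated genes were drawn independently, with the same SD in both groups and fewer changed genes than the 2429 called here. These rates therefore do not cover correlated genes or the larger spread between the R5020 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.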

Results

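Transcripts were measured on 4 Illumina BeadChip arrays in T47D-MTVL cells, a derivative of the hormone-responsive human breast cancer line T47D with a luciferase reporter under the mouse mammary tumour virus promoter. The cells also held a doxycycline-controlled KRAB repressor with a red fluorescent marker and an empty vector for short hairpin RNA, and doxycycline was withheld. After 2 days without serum, they received 10 nM R5020, a synthetic progestin, or ethanol vehicle for 6 h. Each group had 2 arrays, labelled as biological replicates. The arrays gave values for 22177 probes, from which 16577 genes were tested, and the array medians lay between 7.28 and 7.29 on the deposited log2 scale. Across all probes, which are not independent replicates, Pearson's r was 0.999 between the vehicle arrays, 0.996 between the R5020 arrays and 0.983 to 0.984 between arrays of different groups. The number of arrays limits the precision of every value.

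The comparison of R5020 with vehicle asks which transcripts change within hours of progestin exposure. Known progestin targets such as FKBP5, TIPARP and SGK1 rose by over 6-fold. Transcripts of the luminal transcription factors FOXA1, ELF3 and GATA3 fell, as did those of the progesterone receptor PGR and the estrogen receptor ESR1. In limma, at a Benjamini-Hochberg adjusted p under 0.05, 1149 genes were higher and 1280 were lower after R5020, together 14.7% of the genes tested. Increases were the larger changes: 174 called genes rose by at least 2-fold and 39 fell by at least 2-fold, and at 4-fold the counts were 21 and 2. All 2429 called genes had both R5020 values on the same side of both vehicle values, as did 8281 (49.95%) of all genes, where chance gives 33.3%. When the median change of genes above the probe median was taken off, an alternative chosen after seeing the data, 1335 genes were higher and 948 lower, so that 58.5% of calls were increases, compared with 47.3% on the values as deposited. With all arrays, 4382 genes had an unadjusted p under 0.05 in limma. Without vehicle 1, vehicle 2, R5020 1 or R5020 2, a group is a single array and the other group alone gives the spread. Genes can hardly pass in such fits, so their calls decide nothing about single arrays. The alternatives with 1 value per gene, these fits among them, kept the log2 change of TIPARP between 2.97 and 3.1. VAV3 stayed between -2.46 and -2.23, and F3 ran from 1.08 to 1.58.

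**Figure D1:**
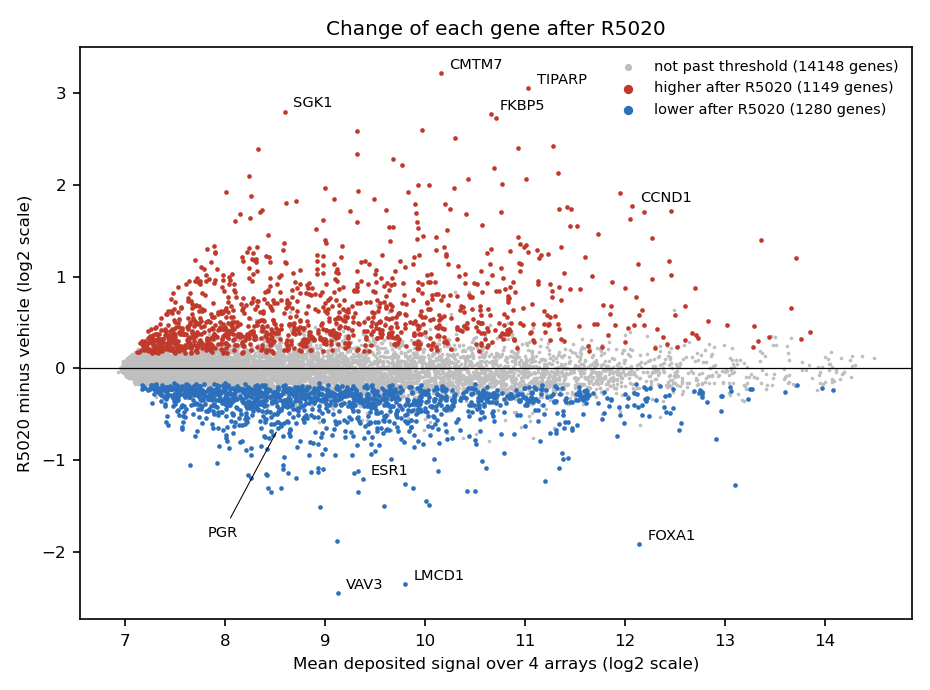
Log2 change (R5020 minus vehicle, vertical axis) of each of 16577 genes against its mean deposited log2 signal over the 4 arrays (horizontal axis); red points are the 1149 genes called higher, blue points the 1280 called lower and grey points genes not past the threshold. The red points reach 3.22 (CMTM7) and the blue points reach -2.45 (VAV3).

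The largest increase was that of CMTM7, a MARVEL-domain transmembrane protein gene, from 8.55 ± 0.04 to 11.77 ± 0.20 (SD, n = 2 each). This is a log2 change of 3.22 (SE 0.10, adjusted p = 0.000628), or 9.32-fold. A second, dimmer CMTM7 probe changed by 1.51. TIPARP, which encodes a mono-ADP-ribosyltransferase, rose 8.31-fold (log2 change 3.06, SE 0.0478, adjusted p = 0.000227). SGK1, a steroid-induced kinase, rose 6.96-fold on the deposited scale from a vehicle mean of 7.2, below the median probe, where folds can be understated. FKBP5, a co-chaperone of steroid receptors, rose 6.82-fold from 9.28 ± 0.01 to 12.05 ± 0.07. The transcriptional coactivator gene CITED4 rose 6.61-fold, the interleukin receptor subunit gene IL20RA 6.00-fold and the calcium-binding protein gene S100P 5.72-fold. FAM107B rose 5.37-fold, ZNF689 5.30-fold, SYBU 5.05-fold and CLCC1 6.04-fold. SCRG1 rose 5.24-fold from a vehicle mean of 7.14, also below the median probe. The 2 CLCC1 probes disagreed, since the dimmer one changed by -0.11 with an adjusted p of 0.263.

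The largest decrease was that of VAV3, a guanine nucleotide exchange factor gene, from 10.35 ± 0.01 to 7.90 ± 0.01 (SD, n = 2 each). This is a log2 change of -2.45 (SE 0.0364, adjusted p = 0.000227), 5.46-fold lower. LMCD1, which encodes a LIM-domain protein, was 5.10-fold lower. FOXA1, a pioneer transcription factor of luminal breast cells, fell from 13.10 ± 0.08 to 11.19 ± 0.13, a log2 change of -1.92 (SE 0.0816, adjusted p = 0.00087). ARID5B was 3.68-fold lower and SRARP, a steroid receptor-associated protein gene, 2.85-fold lower. The ETS transcription factor genes ELF3 and ELF5 were 2.54-fold and 2.53-fold lower. The iron transporter gene SLC11A2 was 2.52-fold lower, CCNO 2.73-fold, MYRFL 2.83-fold, VASN 2.80-fold and the scaffold protein gene DLG2 2.54-fold, with a second DLG2 probe near the floor that changed by -0.05.

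**Figure D2:**
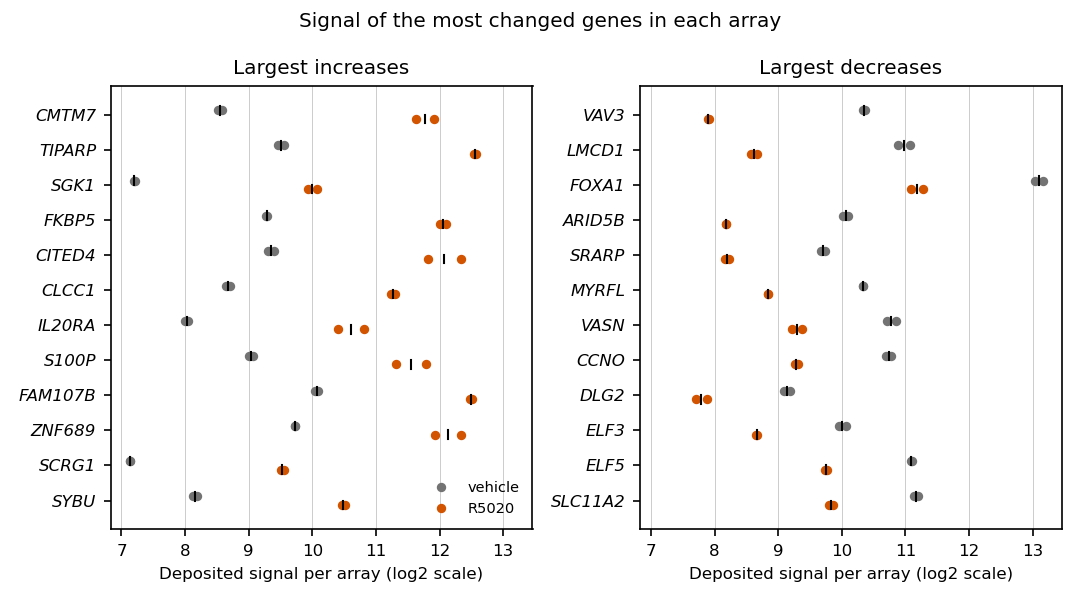
Deposited log2 signal (horizontal axes) of the 12 called genes with the largest increase (left) and the 12 with the largest decrease (right) in each array; grey points are the 2 vehicle arrays, orange points the 2 R5020 arrays and black bars the mean of each group. The 24 genes were chosen among those whose groups do not overlap, so their R5020 and vehicle points lie apart by selection. For FOXA1 the mean was 11.19 after R5020, against 13.10 in vehicle.

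The transcript of the R5020 receptor was lower. PGR fell from 8.86 ± 0.03 to 8.21 ± 0.06 (SD, n = 2 each), a log2 change of -0.66 (SE 0.0478, adjusted p = 0.00276) or 1.57-fold. ESR1 was 2.31-fold lower (adjusted p = 0.00123) and the coactivator gene NCOA1 rose 1.34-fold. These were the 3 of 9 measured steroid receptors and coregulators that changed (1 rose and 2 fell, also when adjusted over the list alone), and camera gave an adjusted p of 0.705 for the list.

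Of 30 progestin targets, a list fixed before the data were examined, 21 rose and 2 fell (23 and 3 adjusted over the list alone), with a median log2 change of 1.07. The stress-response gene NDRG1 rose 4.64-fold and NET1, another guanine nucleotide exchange factor gene, 4.55-fold. The transcription factor genes CEBPD and STAT5A rose 4.17-fold and 3.04-fold. The glucocorticoid- and progestin-inducible genes TSC22D3, KLF9 and ZBTB16 rose 2.39-fold, 1.74-fold and 1.93-fold. The mammary ETS factor gene ELF5 was 2.53-fold lower and MYC 1.27-fold lower. Changes of BCL2L1 (log2 change 0.64, adjusted p = 0.0966) and CDKN1A (0.40, adjusted p = 0.0532) did not pass. The BCL2L1 change ran from 0.38 to 0.89 over the alternatives, and a second, dimmer BCL2L1 probe rose by 0.68 (adjusted p = 0.0139). Against the other genes, camera gave an adjusted p of 4.99e-16 for the list. The adjusted p was 0.284 with an estimated correlation.

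Among 29 genes of G1/S and DNA replication, 7 rose and 1 fell, with the same counts when adjusted over the list alone. CCND1, the cyclin D1 gene, rose 3.40-fold from 11.19 ± 0.10 to 12.96 ± 0.09 (SD, n = 2 each, adjusted p = 0.000782). The replication factor gene GINS2 rose 2.24-fold, the cyclin E2 gene CCNE2 1.87-fold and UHRF1, which maintains DNA methylation at replication, 1.41-fold. The helicase subunit gene MCM4, named after its values were seen, was 1.25-fold lower. Camera gave an adjusted p of 0.000204 for the list, and 0.375 was the adjusted p with an estimated correlation. Of 25 genes of G2/M and mitosis, 0 rose and 6 fell (7 over the list alone), with a camera adjusted p of 0.0729. TOP2A was 1.4-fold lower, CCNF 1.36-fold, CENPE 1.35-fold and AURKA 1.21-fold. The AURKA call was lost with an intensity trend in eBayes. Of 6 CDK inhibitors, CDKN2B was 2.46-fold lower and CDKN2A 1.31-fold lower and 0 rose. Adjusted over the list alone, 2 rose and 2 fell, and camera gave an adjusted p of 0.966. The CDKN2A call was lost when all probes of a gene were averaged.

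Core histone transcripts were lower: 10 of 16 measured fell and 0 rose (12 fell when adjusted over the list alone). H4C3 was 1.38-fold lower (log2 change -0.47, adjusted p = 0.015), H2AJ 1.25-fold, H2BC5 1.24-fold and H2BC21 1.21-fold. Camera gave an adjusted p of 0.00149 for the list. With an estimated correlation the adjusted p was 0.375. The calls of H2AJ, H2BC5 and H2BC21 were lost with an intensity trend, and histone genes are similar enough in sequence that a probe can read several. Of 7 linker histones, H1-2 was 1.25-fold lower and 0 rose, also over the list alone, with a camera adjusted p of 0.966.

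Of 18 ribosome biogenesis genes, 4 rose and 0 fell (9 and 0 adjusted over the list alone). RRS1 rose 1.44-fold, the RNA helicase gene DDX21 1.4-fold, NOP16 1.38-fold and WDR12 1.26-fold. Camera gave an adjusted p of 0.000132, and the adjusted p was 0.375 with an estimated correlation. Of 25 ribosomal protein genes, RPL37 was 1.19-fold lower and 0 rose, also over the list alone. RPS28 (log2 change -0.31, adjusted p = 0.0919) did not pass. The list had a median log2 change of -0.11, against -0.05 for random lists of the same mean signal. Camera gave it an adjusted p of 0.0194. With an estimated correlation the adjusted p was 0.446, and without vehicle 1 or R5020 2 the camera adjusted p was 0.0898 or 0.177. The list also missed the threshold by fry (0.0896) and with the dim filter (0.0886).

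Of 23 immediate early genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone). KLF6 rose 2.51-fold, ZFP36, which promotes mRNA decay, 2.38-fold, the matricellular protein gene CCN1 1.92-fold and ATF3 1.52-fold. IER3 and EGR1, named after their values were seen, were 1.42-fold and 1.24-fold lower. Camera gave an adjusted p of 0.0206, and the adjusted p was 0.375 with an estimated correlation. Without vehicle 1 or R5020 2 the camera adjusted p was 0.0945 or 0.0657, and with camera on ranks it was 0.0841. Of 19 EGFR ligands, receptors and MAPK feedback genes, 7 rose and 4 fell, also over the list alone, and the camera adjusted p was 0.0916. The EGFR inhibitor gene ERRFI1 rose 3.33-fold, the MAPK phosphatase genes DUSP1 and DUSP4 2.70-fold and 2.28-fold, and SPRED1 2.25-fold. DUSP5, SPRY1, ERBB3 and DUSP10, named after their values were seen, were 2.24-fold, 2.21-fold, 1.99-fold and 1.28-fold lower. The ERBB3 call was lost with an offset of 50 on the linear scale.

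Of 27 genes of the type I interferon response, 8 fell and 2 rose (9 and 2 adjusted over the list alone). OAS2, an antiviral oligoadenylate synthetase gene, was 1.60-fold lower and IFI35 1.31-fold lower, while the transcription factor gene IRF1 rose 1.58-fold and the ISG15 ligase gene HERC5 1.52-fold. Camera gave an adjusted p of 0.0194. The adjusted p was 0.375 with an estimated correlation, and without vehicle 1 or R5020 1 the camera adjusted p was 0.0726 or 0.0797. The list also missed the threshold with the dim filter (0.0614). Of 20 genes of NF-kB and the inflammatory response, 3 rose and 3 fell (3 and 4 over the list alone), with a camera adjusted p of 0.885. The NF-kB inhibitor genes NFKBIA and NFKBIE rose 3.10-fold and 1.41-fold, and SOD2, a mitochondrial superoxide dismutase gene, 2.19-fold. NFKB1 was 1.31-fold lower. NFKB2 and TNFAIP2, named after their values were seen, were 1.25-fold and 1.16-fold lower, and the TNFAIP2 call was lost when the median change was taken off.

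Of 12 luminal epithelial markers, 4 fell and 0 rose, also over the list alone. These were FOXA1 (3.77-fold), ELF3 (2.54-fold), GATA3 (1.73-fold, adjusted p = 0.0152) and the keratin gene KRT18 (1.18-fold), which was named after its values were seen and was lost with an intensity trend. A second KRT18 probe, with a mean of 9.28, changed by -0.64 (adjusted p = 0.00517), against -0.24 for the chosen probe and -0.01 for another probe, with a mean of 7.44. Of 9 basal and progenitor markers, the hyaluronan receptor gene CD44 rose 3.29-fold, EGFR 1.55-fold and SOX9 1.46-fold, and 0 fell (3 and 1 over the list alone). CDH3, the member that fell over the list alone, did not pass over all genes (log2 change -0.275, limma adjusted p = 0.0905). The basal markers KRT6A, KRT6B, KRT17 and TP63 had no probe used here, and the dim filter kept 5 of the 9 measured. Camera gave adjusted p-values of 0.0568 for the luminal and 0.10 for the basal list. Fry, which compares a list with no other genes, gave adjusted p-values of 0.0178 and 0.0168. Among random lists of the same mean signal, the luminal median lay at percentile 29.13 and the basal median at 86.96, so neither median stood out. Of 17 markers of other cell types, such as fibroblasts, leukocytes and endothelium, ACTA2 was 1.33-fold lower and COL1A1 1.27-fold lower, and 0 rose (1 and 2 over the list alone), with a camera adjusted p of 0.966. The ACTA2 call was lost when the median change was taken off. Of 21 adhesion and extracellular matrix genes, 1 rose and 6 fell (2 and 6 over the list alone), with a camera adjusted p of 0.186. THBS1, the thrombospondin gene, rose 2.20-fold, while LAMA5 was 1.56-fold lower, ITGA5 1.43-fold and ITGA2 1.31-fold.

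Estrogen targets moved in both directions: of 18, 3 rose and 4 fell (4 and 4 over the list alone), and the camera adjusted p was 0.885. GREB1, a cofactor of the estrogen receptor, rose 2.64-fold and the chemokine gene CXCL12 1.78-fold. RARA was 2.17-fold lower and IGFBP4 1.49-fold lower. The other GREB1 probes changed by 0.18, 0.28 and 0.06 and the other RARA probes by -0.04 and -0.03, all of them below the median probe, and the mean of probes gave log2 changes of 0.48 for GREB1 and -0.39 for RARA, against 1.4 and -1.12. SIAH2 (1.30-fold higher), TFF3 (1.42-fold lower) and PKIB (1.19-fold lower) were named after their values were seen. The calls of IGFBP4 and TFF3 were lost with an offset of 50, and that of PKIB when all probes of a gene were averaged.

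Of 22 genes of glycolysis and the hypoxia response, 8 rose and 1 fell (9 and 3 adjusted over the list alone). PFKFB3, which makes an activator of glycolysis, rose 3.53-fold (log2 change 1.82, adjusted p = 0.00107), BNIP3 1.82-fold, the lactate dehydrogenase gene LDHA 1.58-fold and the glucose transporter gene SLC2A1 1.56-fold. EGLN3, named after its values were seen, was 1.32-fold lower. Camera gave an adjusted p of 0.0227, and the adjusted p was 0.375 with an estimated correlation. Without vehicle 1, R5020 1 or R5020 2 the camera adjusted p was 0.0898, 0.0638 or 0.147, and with camera on ranks it was 0.176. Of 23 genes of fatty acid synthesis and lipid storage, 4 rose and 2 fell, also over the list alone, with a camera adjusted p of 0.0614. ACSL1, which activates fatty acids, rose 2.20-fold, the lipid droplet protein gene PLIN2 2.04-fold and the elongase gene ELOVL1 1.65-fold. SCD (1.32-fold higher), GPAM (1.31-fold lower) and LPIN1 (1.16-fold lower) were named after their values were seen, and the LPIN1 call was lost with an intensity trend. Of 19 cholesterol synthesis genes, 3 rose and 1 fell (6 and 3 over the list alone), with a camera adjusted p of 0.0916. IDI1 and SQLE rose 1.5-fold each and MSMO1 1.4-fold. HSD17B7, with the largest absolute change of the list, was lower but did not pass (log2 change -0.70, limma adjusted p = 0.0760). TM7SF2, named after its values were seen, was 1.32-fold lower, and the IDI1 call was lost with an offset of 50. Of 15 ion and water transport genes, 5 rose and 0 fell (5 and 1 over the list alone), with a camera adjusted p of 0.0597. Besides SGK1, the sodium pump subunit gene ATP1B1 rose 3.39-fold, NEDD4L 1.34-fold and the potassium channel gene KCNK1 1.27-fold. The sodium channel subunit gene SCNN1G, named after its values were seen, rose 1.15-fold.

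**Figure D3:**
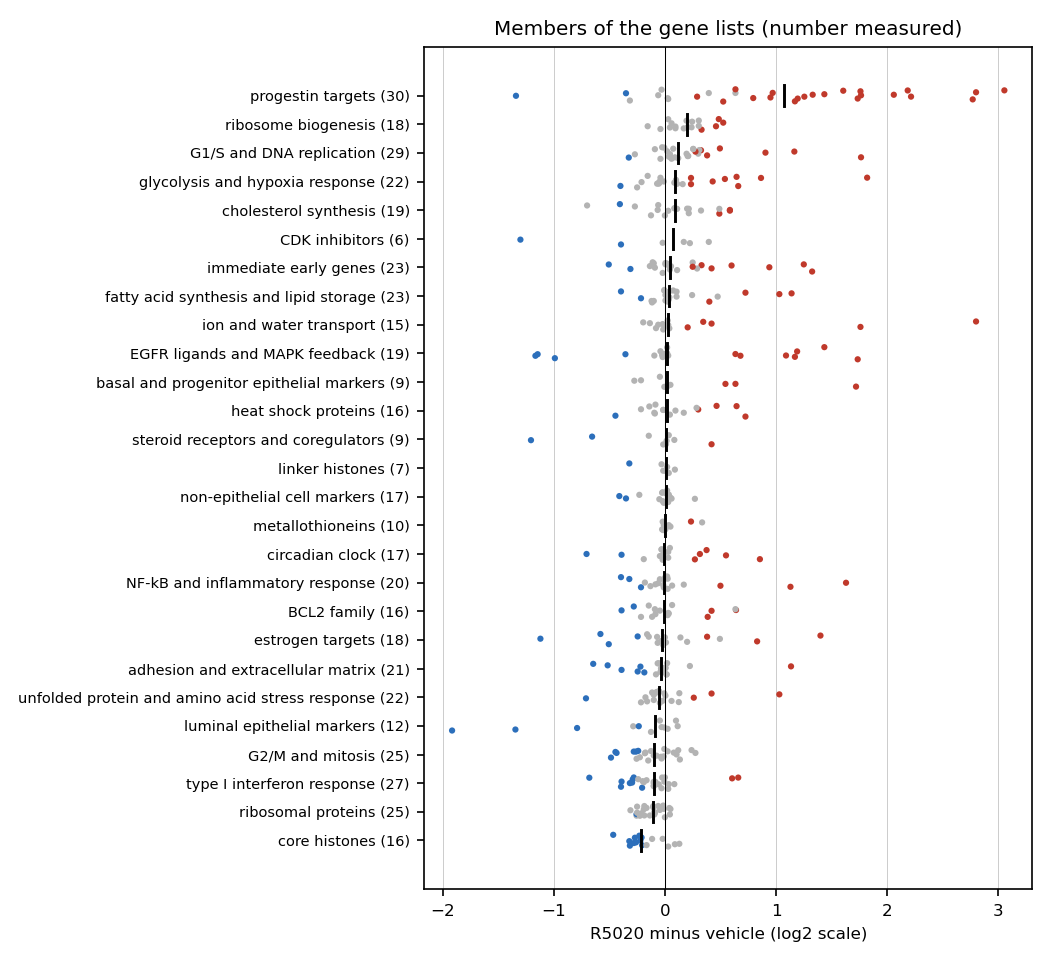
Log2 change (R5020 minus vehicle, horizontal axis) of each measured member of the 27 gene lists, with the number measured in brackets; red points are members called higher, blue points members called lower, grey points members not past the threshold and black bars the list medians. Progestin targets have the highest median (1.07) and core histones the lowest (-0.22).

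Of 17 circadian clock genes, 5 rose and 2 fell (5 and 3 over the list alone), with a camera adjusted p of 0.380. The repressor gene NFIL3 rose 1.81-fold and PER2 1.46-fold, and BHLHE40 was 1.63-fold and TEF 1.31-fold lower. CRY2, CIART and CRY1, named after their values were seen, rose 1.30-fold, 1.24-fold and 1.21-fold. The PER2 call was lost with an offset of 50 and the CRY1 call with an intensity trend. Of 22 genes of the unfolded protein and amino acid stress response, 3 rose and 1 fell, also over the list alone, with a camera adjusted p of 0.966. CEBPG rose 2.04-fold, and the endoplasmic reticulum chaperone genes DNAJB9 and DNAJC3 1.34-fold and 1.2-fold. The stress transcription factor gene DDIT3 was 1.64-fold lower. Of 16 heat shock genes, 4 rose and 1 fell (5 and 1 over the list alone), with a camera adjusted p of 0.402. DNAJB1 rose 1.65-fold, BAG3 1.56-fold, HSPB8 1.38-fold and HSPH1, named after its values were seen, 1.23-fold, and HSPA1B was 1.36-fold lower. Of 16 BCL2 family genes, 3 rose and 2 fell (4 and 3 over the list alone), with a camera adjusted p of 0.885. BMF, which promotes apoptosis, rose 1.56-fold and MCL1, which opposes it, 1.34-fold, while BIK was 1.31-fold lower. A second MCL1 probe, with a mean of 8.13, changed by 0.06 (adjusted p = 0.712), and the mean of probes gave log2 changes of 0.24 for MCL1 and 0.24 for BMF, against 0.42 and 0.64. HRK (1.31-fold higher) and BCL2L2 (1.21-fold lower) were named after their values were seen. Of 10 metallothioneins, MT1X rose 1.18-fold and 0 fell (2 and 0 over the list alone), with a camera adjusted p of 0.267. MT2A had the largest change but did not pass (log2 change 0.335, limma adjusted p = 0.0523). Most other metallothioneins lay below the median probe, where a change is hard to see. With the dim filter, this list, linker histones and markers of other cell types kept too few members for camera, and the NF-kB list kept 8.

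Of the 27 lists, 5 were higher and 3 lower by camera with its preset correlation, and 0 passed with an estimated correlation. In the latter, 2 (progestin targets, and G1/S and DNA replication) had an unadjusted p under 0.05. With so few degrees of freedom, this does not show that correlation among genes undoes a list. Among called lists, the estimate lay below the preset 0.01 for progestin targets (-0.0222), G1/S and DNA replication (-0.0282), glycolysis (-0.0462) and core histones (0.00757). It lay above 0.01 for the immediate early (0.0493), interferon (0.0392), ribosomal protein (0.12) and ribosome biogenesis (0.0176) lists. In 9 lists, none past the threshold, the median, the mean and the test differed in sign: steroid receptors, estrogen targets, CDK inhibitors, circadian clock, NF-kB, unfolded protein response, BCL2 family, linker histones and markers of other cell types.

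The choice of probe set the size of several changes. Averaging all probes of a gene made the log2 change of 27 named genes over 1.5 times smaller and turned the sign of 0, and in 15 of them no other probe lay above the median probe. Among increases, the mean of probes gave 1.25 for CLCC1, 0.42 for TSC22D3, 0.19 for EGFR, 0.45 for CCNE2, 0.30 for ATF3, 1.05 for CD44, 0.74 for SOD2 and 0.26 for NCOA1. Among decreases, it gave -0.70 for DLG2, -0.36 for OAS2, -0.59 for SPRY1, -0.64 for CDKN2B, -0.50 for ERBB3 and -0.23 for DUSP10. It ended the calls of H2BC5, CDKN2A, PER2 and PKIB. TFF3, which has 1 probe and a limma adjusted p of 0.0499, also lost its call in that fit, although its values were the same. Taking off the median change ended the calls of H2AJ, H2BC21, IGFBP4, ACTA2, TFF3, TNFAIP2 and KRT18. Besides SGK1 and SCRG1, a group mean below the median probe was found in vehicle for HERC5, SCNN1G and the progestin targets ZBTB16, F3, PDK4 and IRS2, and after R5020 for EGR1 and TNFAIP2.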

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

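The test of replicate spread in little-changed genes and the counts with an offset taken off were chosen after the results were seen, and the other tests of this part were set out before their results were known.

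Probes without a gene name lie outside the gene comparison, and some carried a response: of 2469 such probes, 97 were higher and 115 lower after R5020 in the limma fit over all probes. That is 8.59% of them, against 13.2% of probes with a gene name, and 37.2% of the unnamed probes lay above the probe median, against 51.5% of the named ones. The largest increase over all probes was that of an unnamed one, ILMN_1764709, from 7.87 ± 0.03 to 11.52 ± 0.08 (SD, n = 2 each), a log2 change of 3.65 (adjusted p = 0.000162). ILMN_1775566 changed by 1.78, ILMN_1729311 by -1.46 and ILMN_1761762 by -1.24. These 4 probes were chosen after their values were seen.

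The R5020 arrays differed more from each other than the vehicle arrays did. The SD of the replicate difference over genes above the probe median was 0.164 for R5020 and 0.0889 for vehicle. A stronger response in one of the cultures is argued against, since across called genes the difference between the R5020 arrays was nearly unrelated to the log2 change (Pearson's r = 0.0313 across 2429 genes, which are not independent). A normalization curve that depends on signal is argued against as well, because the ratio of SDs was 1.84 after a lowess curve was taken out. In 3650 genes with little change the ratio was 1.89, so the extra spread may lie over all genes. Whether it arose in a culture or on an array stays open.

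Large increases outnumbered large decreases, and 81.7% of the called changes of at least 2-fold were increases. The floor of the scale, which hides decreases of dim genes, is argued against as the whole cause. Among genes with a vehicle mean of at least 9.29, 69 such changes were increases and 27 decreases, or 71.9% (95% exact binomial interval 61.8% to 80.6%, which treats genes as independent). The median log2 change of genes above the probe median was -0.04, but the authors' normalization had already given the arrays nearly equal medians, so that a value near 0 decides nothing. Taking it off left 186 increases and 37 decreases of at least 2-fold, or 83.4% increases, which for the same reason decides nothing about an offset. To balance changes of at least 2-fold, here counted over all genes whether called or not, the R5020 arrays would have to read 0.255 too high. Then 87.4% of genes above the probe median would be lower after R5020. Without controls of known amount, an offset hidden by so general a fall cannot be told apart. Slow loss of stable mRNA within 6 h and a response that is mostly activation were not tested.

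Ribosomal protein and core histone transcripts were lower by camera with its preset correlation, with 1 of 25 and 10 of 16 genes called. With an estimated correlation, and so few degrees of freedom, the adjusted p was 0.446 and 0.375. The ribosomal protein list also missed the threshold by fry (adjusted p = 0.0896) and with the dim filter (0.0886). For ribosomal proteins, a trend over abundant transcripts is consistent with the data, since their median lay at percentile 11.5 of random lists with the same mean signal. For core histones the same trend is argued against, with a median at percentile 0.11. Reading of several histone genes by 1 probe was not tested, so a lower level of histone mRNA after R5020 remains a hypothesis.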

How the results depend on the processing

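Array weights, taking off the median change and the intensity trend in reduced fits were chosen after seeing the data. Both gene counts stayed within 1.5 times of 1149 and 1280 under the dim filter, quantile normalization, median centring, an intensity trend, a robust prior, the mean of probes, all probes as features, an offset of 50, array weights and taking off the median change, ranging from 1089 to 1366 higher and from 948 to 1452 lower. Counts alone do not show that the same genes passed. Among these settings with 1 value per gene, an intensity trend kept the fewest of the 1149 higher genes, 1058. Taking off the median change kept the fewest of the 1280 lower genes, 948. An adjusted p under 0.01 left 583 higher and 363 lower, and a fold change of at least 1.5 left 449 and 189. Leaving out each array in turn gave 0 to 0 genes in each direction in limma, with 2490 to 4415 genes at an unadjusted p under 0.05 and lowest adjusted p-values of 0.0785 to 0.210. Such fits leave 1 array in a group, so the spread comes from the other group alone and few genes can pass whatever their change. With an intensity trend they also called 0 genes, with 2231 to 4442 at an unadjusted p under 0.05. No named gene changed direction in the settings with 1 value per gene. Over all probes, 1 called gene among those named, N4BP2L2, also had a probe past the threshold the other way. The dimmer probes of MECOM and CLCC1, above the probe median, had the opposite sign without passing it. Below the probe median, probes of further named genes also had the opposite sign, such as 1 of TSC22D3 (-0.055 against 1.255) and 1 of CDKN2B (0.015 against -1.3).

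The arrays share replicate numbers, and the deviations of equally numbered arrays correlated at 0.208 across all probes, but 2 pairs cannot show that the numbers pair the samples. With the replicate block, limma called 0 genes higher and 0 lower, with 4070 at an unadjusted p under 0.05, and with an intensity trend as well 0 and 0, with 3883. These fits had 2.22 and 2.40 total degrees of freedom, against 4.65 in the main fit. A lack of calls therefore cannot show that the replicate number matters. The block left the list counts at 5 higher and 3 lower.

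Of the gene lists, 5 were higher and 3 lower. Camera with an estimated correlation, which has few degrees of freedom, gave 0 and 0 (2 at an unadjusted p under 0.05). Fry gave 10 and 6, camera on ranks 3 higher, and the dim filter 1 lower. By fry, lists that camera missed also passed: G2/M and mitosis, EGFR and MAPK feedback, steroid receptors, estrogen targets and adhesion genes. So did fatty acid synthesis, ion transport, and luminal and basal markers. Leaving out each array in turn gave 3 to 5 higher and 1 to 4 lower, and progestin targets, G1/S and DNA replication, ribosome biogenesis and core histones passed in all 4 such fits. The causes were not tested. Signal near the floor limits dim genes: 191 called genes had a group mean not above the median probe.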

Other observations

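The genes of this part were chosen after their values were seen, and their adjusted p-values come from the same limma fit. Beyond the lists, several transcription factor genes changed by over 2-fold. CEBPA, a regulator of differentiation, rose from 10.27 ± 0.12 to 12.40 ± 0.10 (SD, n = 2 each), 4.39-fold with an adjusted p of 0.000718. The epithelial factor gene GRHL2 rose 3.46-fold, SOX4 3.23-fold, RUNX1 2.45-fold, the Wnt pathway factor gene LEF1 2.39-fold and the vitamin D receptor gene VDR 2.11-fold. MECOM was 2.46-fold lower and ID3, an inhibitor of helix-loop-helix factors, 2.19-fold lower. EHF, an epithelial ETS factor gene like ELF3 and ELF5, was 1.77-fold lower (adjusted p = 0.00837). With the mean of probes, the log2 change was 0.52 for RUNX1, 0.62 for VDR and -0.59 for MECOM, against 1.29, 1.08 and -1.30 with the chosen probe. A second MECOM probe, slightly above the median probe, changed by 0.13 (adjusted p = 0.171).

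CLDN1 and CLDN3, which encode tight junction proteins, were 2.42-fold and 1.97-fold lower, CLDN1 from a vehicle mean of 13.74 ± 0.01 (SD, n = 2). HILPDA, a lipid droplet protein gene, rose 2.94-fold, while the lipase inhibitor gene ANGPTL4 was 2.19-fold lower, with a log2 change of -0.60 from the mean of its probes against -1.13.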
